A study of Mus musculus with 12 samples.

How the data were processed

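Gene expression was measured in ovaries of neonatal Swiss mice, excised at day 3 to 4 and cultured for 96 hours (4 days) with vehicle (0.1% DMSO) or 1 of 3 agents. The series description gives the age of day 3 to 4. The last day in the sample labels' age instead increases by 1 from array to array, from 4 (control 1) to 15 (MEN 3), which was taken for an error of entry; read literally, it would confound age with group. The agents were 4-vinylcyclohexene diepoxide at 50 µM (VCD), methoxychlor at 50 µM (MXC) and menadione at 5 µM (MEN). Each of the 4 groups had 3 arrays, 12 in all, of the Affymetrix Mouse Genome 430 2.0 type, hybridised with biotin-labelled RNA per the labels' protocols. The labels number the arrays within a group but do not say whether these came from separate cultures or animals. The p-values given here therefore measure the spread between these samples, which may in part be technical.

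The table of probe set values deposited by the authors holds an intensity (signal) per array on a linear scale with 1 decimal. The submitters' processing notes name RMA and Partek. The values of this table are not on an RMA scale: 235 of them are 0, the largest is 11113.3, and the mean without the lowest and highest 2% of probe sets is 150.0 on every array, as the array maker's scaled signal has. The algorithm behind the table is not given in the sources used here. The design written before the data were examined had assumed log2 values from RMA. It was kept, with the signals transformed to log2(signal + 16). A change on this scale understates the change of dim probe sets.

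For each agent the authors deposited a table of all probe sets, a list of changed probe sets and a Gene Ontology table. Per the file headers, the table and the list of probe sets hold an unadjusted p-value, a linear ratio of control over agent, and a signed fold score that is negative where the agent was higher. The deposited Gene Ontology tables give an enrichment score per term, whose definition is not given in the sources used here. These tables come from another normalization than the value table and hold no value per array. They were used only for description.

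Of 45101 probe sets, 64 controls of the array maker were left out of the tests and 45037 were tested, with no filter on dim ones. Gene symbols and positions are those of the array maker's annotation in the files (mouse NCBI Build 36). Of all probe sets, 36872 named 1 gene, 2276 several and 5953 none. Through their Entrez identifier 33063 probe sets of 1 gene were matched to a table of RefSeq genes (GRCm38.p6), which updated 5927 symbols. No position was taken from that table. A gene named here is represented by 1 probe set in each comparison, and its other probe sets are reported where they differ.

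All 12 arrays were fitted together with a mean per group in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual degrees of freedom and 10.17 after moderation. Tests were two-sided. Benjamini-Hochberg adjustment ran over the 45037 probe sets of each comparison, with a threshold of adjusted p under 0.05. Each agent was compared with control, and each pair of agents with each other in the same fit. Errors printed after ± are standard errors (SE) of the fit unless SD is named, and 95% intervals come from the same fit. The number of arrays, 3 per group, limits the precision. The replicate numbers of the labels, by the rule that every same-number pair correlates above 0.1 in deviations from group means, paired control with MXC (0.249, 0.371 and 0.468) but no other pair of groups; number 3 marks the most degraded array of both. With the number as a block, the count for MXC was 0 as without it. An exact permutation test of 3 against 3 arrays cannot go below a two-sided p of 0.1.

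For 30 gene lists fixed before the data were examined, a shift of the whole list was tested with limma's camera at a preset inter-gene correlation of 0.01. The tests were repeated with an estimated correlation and with fry. Adjustment ran over the 90 tests of 30 lists and 3 agents. A list used the probe set with the highest mean for each of its genes. A set of 4 further lists was written after a first look at single probe sets. It was adjusted as a separate, smaller family and appears only in the closing section. Named genes follow a rule fixed beforehand. For each agent these were up to 10 of the largest rises and 10 of the largest falls among probe sets of 1 gene past the threshold, with all treated arrays on 1 side of all control arrays. Up to 4 members past the threshold were named per list, and 5 differences each way per pair of agents. A fixed panel of follicle, steroid and stress genes was named whatever its values.

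The 3 comparisons with control share their control arrays. Unchanged groups were therefore simulated in 100 draws, of which 20 also counted calls. All 12 arrays, controls included, were drawn as noise with each array's own spread. The 3 comparisons shared the simulated controls, and the noise was independent between probe sets. The procedure was tested on simulated data in which 50 probe sets per fold size were changed. With all 45037 probe sets fitted, it called 56% of 2-fold and 88% of 4-fold changes for VCD, 68% and 90% for MXC, and 50% and 84% for MEN. No unchanged probe set was called. At 1.5-fold the shares were 6%, 8% and 12%. In a simulation of 20000 genes, a list shifted by 0.5 on the log2 scale was called in all 3 comparisons and no other list was. Both simulations drew probe sets or genes independently, so they cannot show the false calls that correlated genes may give.

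RNA integrity was read from the array maker's actin and GAPDH probe sets as the ratio of signal at the 3′ end to that at the 5′ end. Arrays were also divided into 2 classes by the mean of the 3 probe sets for mouse 18S ribosomal RNA, at the widest gap between arrays. No date, batch or scanner is given in the sources used here. Alternatives fixed beforehand were quantile normalization, subtraction of each array's median, removal of dim probe sets, fits of the compared groups alone, the replicate number as a block, other variance models, stricter thresholds, 1 probe set per gene, other set tests and leaving out each array. Further alternatives, added after seeing the data, were other pseudocounts (1 and 32), the actin difference as a covariate, removal of degraded arrays, and the 18S class as a block or restricted to 1 class. Only MEN held arrays of both classes, so with the class as a block its term rested on MEN 2 against MEN 1 and 3. Figures were drawn in Python 3.11.15.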

Results

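The data comprised 12 arrays of whole mouse ovaries, 3 each of vehicle control, VCD, MXC and MEN. VCD is an epoxide known to destroy small ovarian follicles, MXC an organochlorine insecticide, and MEN (vitamin K3) a quinone that generates reactive oxygen by redox cycling. Concentrations had been chosen by the submitters in pilot work to give overt toxicity. The comparisons ask which transcripts each agent changed against vehicle and how the agents differed. Median signal per array lay between 23.6 and 33.4.

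The arrays differed in RNA integrity and in ribosomal RNA signal. Control replicate 3 had an actin 3′ to 5′ signal ratio of 35.8 and a GAPDH ratio of 20.0, whereas the other 11 arrays lay between 1.31 and 5.34 for actin, the highest being MXC replicate 3. Across probe sets, control replicate 3 correlated with the other arrays at 0.883 to 0.938, and every other pair of arrays at 0.952 or more. The first principal component held 46.1% of the variance and followed the actin difference across the 12 arrays (Pearson r = 0.933, permutation p = 0.00048; Spearman rho = 0.923, permutation p = 3e-05). Without control 3 and MXC 3, r was 0.873. The 18S ribosomal RNA probe sets averaged 6.20 to 6.91 (log2) on 5 arrays, all 3 controls and MEN replicates 1 and 3. They averaged 8.56 to 9.94 on the other 7, all VCD and MXC arrays and MEN replicate 2. VCD and MXC therefore lay wholly in the high 18S class and control wholly in the low one. MEN and control shared the low class, and VCD and MXC shared the high one.

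**Figure D1:**
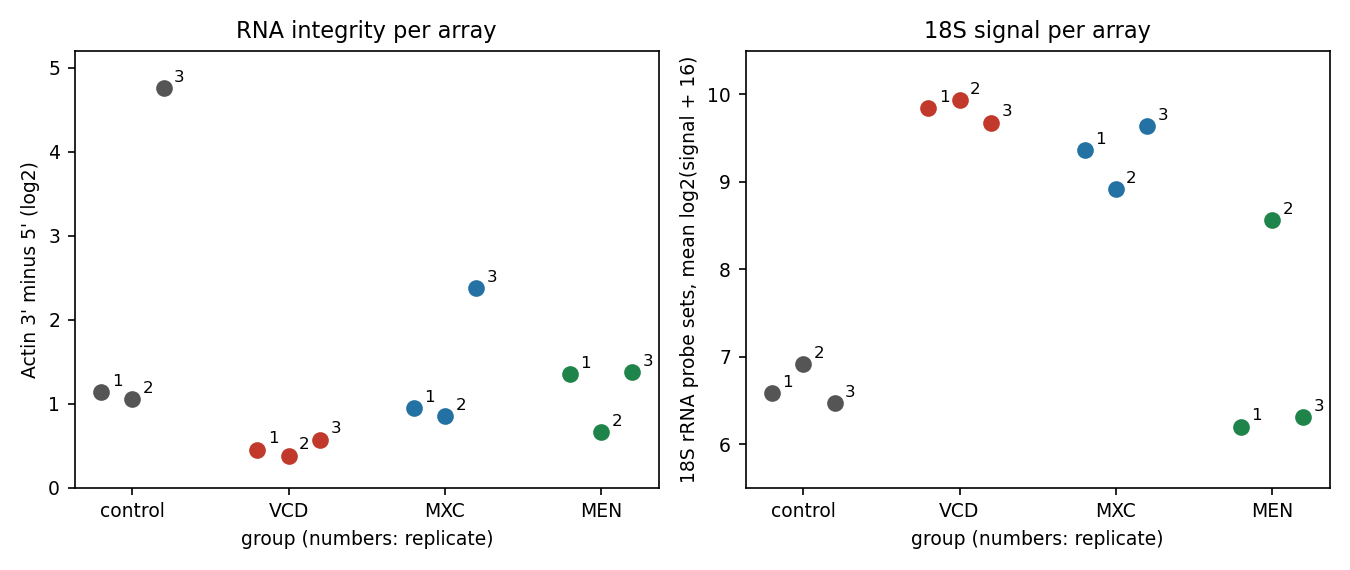
Left, log2 signal difference between the 3′ and 5′ actin control probe sets for each array; right, mean log2(signal + 16) of the 3 probe sets for 18S ribosomal RNA. Each point is 1 array with its replicate number. Control 3 stands apart in integrity, and controls with MEN 1 and MEN 3 lie below 6.92 in 18S signal.

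With VCD, 181 probe sets rose and 2 fell against control, and they represented 136 named genes. The largest rises were Sox4 (chr 13 29042518–29045580), a transcription factor of developing tissues, by 4.10 ± 0.69 on the log2 scale (adjusted p = 0.0439), and Rbbp4, a histone-binding subunit of chromatin complexes, by 3.89 ± 0.61 (adjusted p = 0.0391). The control mean of this Sox4 probe set, 4.2, lay near the floor of 4 set by the pseudocount. Malat1, a nuclear long noncoding RNA, rose by 3.33 ± 0.32 (adjusted p = 0.0162), from 5.03 ± 0.19 (SD, n = 3) in control to 8.36 ± 0.47 with VCD. Btg2, an antiproliferative gene that responds to p53, rose by 2.70 ± 0.39. The falls were Tbc1d9, by 0.75 ± 0.12, and Cep170b, a centrosomal protein gene, by 0.66 ± 0.11 (adjusted p = 0.0391 and 0.0405). The 18S signal of every VCD array was in the high class and that of every control in the low class.

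Other rises named by the fixed rule were the chromatin remodeller Atrx (2.17 ± 0.34), the Max-binding factor Mga (2.31 ± 0.36), Sbno1 (2.72 ± 0.46) and Zfp451 (2.17 ± 0.30). The zinc transporter Slc39a6 rose by 2.39 ± 0.42 and the microtubule-associated Tacc1 by 2.29 ± 0.32. Many of these genes had several probe sets that did not move alike. Both other probe sets of Malat1 were also called, as was 1 of 3 for Rbbp4 and 1 of 7 for Atrx. None of the 7 others for Sox4, the 4 for Mga or the 4 for Zfp451 was called, and 3 of those for Zfp451 had the opposite sign. Control means of Sox4, Atrx (4.53), Mga (4.82), Malat1, Zfp451 (5.30) and Slc39a6 (5.37) lay below the median probe set (5.47), so the sizes of these rises depend on the pseudocount. The median signal of VCD arrays exceeded that of controls by 0.21 (log2), so subtracting array medians lowers each VCD change by that amount. The rises named here exceed it. Over all probe sets with an unadjusted p under 0.05, 4356 were higher and 1106 lower with VCD as deposited, 2924 and 3563 after quantile normalization, and 2121 and 11510 after subtraction of array medians. Both scalings centre the arrays, which by itself moves this balance.

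Of the 30 gene lists, the extracellular matrix list was shifted down with VCD (31 genes, median log2 −0.27, camera adjusted p = 0.0101). With an estimated correlation its adjusted p was 0.676. None of its 31 members passed, over all probe sets or adjusted over the list alone. Members lay at −1.03 ± 0.37 (Col12a1), −0.58 ± 0.26 (Col3a1) and −0.58 ± 0.23 (Fbn1, fibrillin), and the matrix protease gene Mmp14 at 1.43 ± 0.48. The ribosomal protein list had a median of −0.30 (adjusted p = 0.061). At the probe set with the highest mean, which the lists use, no member of any fixed list passed with VCD over all probe sets. Btg2, a member of the p53 target list, was called at another of its probe sets (2.70 ± 0.39, adjusted p = 0.0315). Adjusted over the list alone, 1 member passed in each of the granulosa cell, steroidogenic, estrogen response and inflammation lists. Foxl2, the granulosa cell transcription factor, stood at 1.48 ± 0.31 (adjusted p = 0.0714; control mean 4.27, below the median probe set). Of the panel, Gdf9, Zp3, Nobox, Figla and Kit lay between −0.30 ± 0.17 (Kit) and 0.43 ± 0.41 (Nobox). Among them the zona pellucida gene Zp3 was at −0.28 ± 0.19 and Gdf9 at −0.09 (95% interval −0.49 to 0.31). The lowest of the panel was Mtor at −0.74 ± 0.28 (adjusted p = 0.302), whose 2 other probe sets had the opposite sign. The antioxidant genes Hmox1 and Nqo1 were at 0.56 ± 0.29 and 0.11 ± 0.15. Without control 3, Zp3 lay at −0.06, Nobox at −0.21, Hmox1 at 0.17 and Nqo1 at 0.21. The count of 183 depended on single arrays and on scaling. It was 0 without control 1, VCD 1 or VCD 2, 3 without control 2, 8 without VCD 3 and 682 without control 3. After quantile normalization it was 2, and after subtraction of array medians 17. With the 18S class as a block it was 0. The class term of that fit rests on MEN 2 against MEN 1 and 3 alone, so this 0 cannot show whether the 183 depend on class. After quantile normalization the 181 rises had a median of 1.08, against 1.26 as deposited (median SE 0.191 and 0.192), and adjusted p-values of 0.0223 to 0.207.

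**Figure D2:**
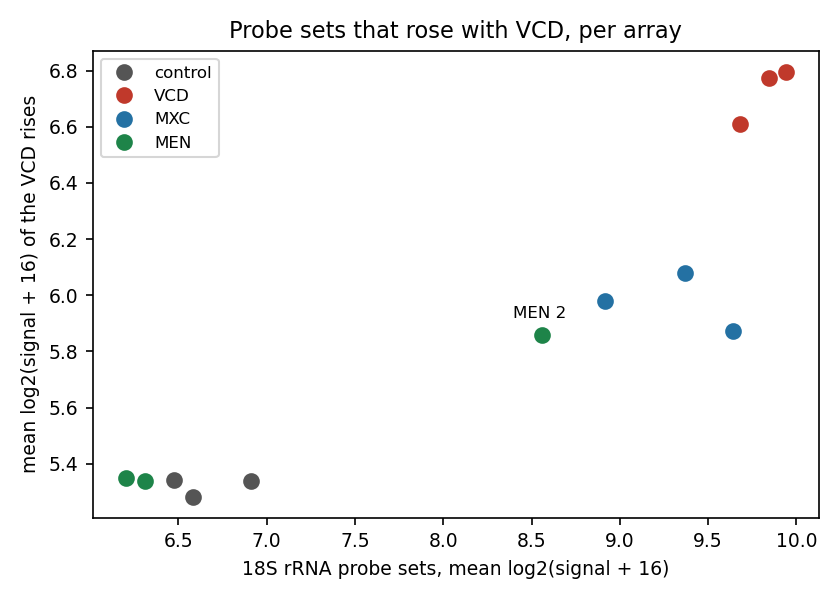
Mean log2(signal + 16) of the 181 probe sets that rose with VCD (vertical axis) against the mean log2 18S ribosomal RNA signal (horizontal axis); each point is 1 array, coloured by group. VCD arrays lie at 6.61 to 6.80, MXC arrays at 5.87 to 6.08, MEN 2 at 5.86, and the 5 arrays of low 18S signal at 5.28 to 5.35.

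With MXC, no probe set passed the threshold against control in limma. The smallest adjusted p was 0.382, and 4269 probe sets had an unadjusted p under 0.05. An unmoderated analysis of variance also called 0, and limma with array weights called 2701. These weights were 5.64 for MXC 1, 0.979 for MXC 2 and 0.272 for MXC 3, so the weighted MXC mean rested mostly on 1 array. In the simulated data 68% of 2-fold changes had been called, but with 50 probe sets changed at each fold size, up to 8-fold. Such changes ease the adjusted threshold, so this share does not say what could be called for MXC. Xist, at 2.35 ± 0.29 with MXC, had an adjusted p of 0.382. Every MXC array was in the high 18S class and every control in the low one, so class and agent cannot be told apart here.

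The hypoxia and glycolysis list was shifted down with MXC (27 genes, median log2 −0.39, camera adjusted p = 2e-05; adjusted p = 0.676 with an estimated correlation). No member passed singly. Egln3, a hypoxia-induced prolyl hydroxylase gene, lay at −1.64 ± 0.50, Adm at −1.22 ± 0.59, Ero1a at −0.97 ± 0.36, Vegfa at −0.81 ± 0.25 and Bnip3 at −0.69 ± 0.25, while the glycolytic Pfkl lay at 0.84 ± 0.58. The cholesterol synthesis list was also shifted down (25 genes, median −0.23, mean −0.15, adjusted p = 0.0192; adjusted p = 0.676 with an estimated correlation). None of its members passed over all probe sets and 3 fell when adjusted over the list alone. Values were −0.51 ± 0.13 for Cyp51, against 0.84 ± 0.62 for Ebp. In the panel, Amh, the granulosa cell hormone, stood at 1.69 ± 0.40 (adjusted p = 0.382), Gdf9 at −0.24 ± 0.18, Kit at −0.19 ± 0.17 and Cyp1b1 at −0.40 ± 0.25. The xenobiotic receptor target list had a median of −0.23 (adjusted p = 0.0939) and the estrogen response list 0.01 (adjusted p = 0.519).

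With MEN, 78 probe sets rose and 75 fell, representing 129 named genes. Sfrp2 (chr 3 83570242–83578236), a secreted modulator of Wnt signalling, fell by 3.13 ± 0.23 on the log2 scale (adjusted p = 0.0031), from 10.28 ± 0.37 (SD, n = 3) to 7.15 ± 0.21. Star (chr 8 26917025–26925783), which carries cholesterol into mitochondria for steroid synthesis, fell by 1.92 ± 0.24 (adjusted p = 0.0227), and both of its other probe sets were also called. Genes of macrophages rose: Aif1 by 1.46 ± 0.17, Ms4a7 by 1.73 ± 0.19, Ly86 by 1.53 ± 0.20 and Fcrls by 2.12 ± 0.33. The matrix proteoglycan gene Ogn rose by 2.45 ± 0.35 and the glypican Gpc3 by 2.24 ± 0.28. Among arrays of low 18S signal (MEN 1 and 3 against the controls), Sfrp2 stood at −3.01, Star at −2.06 and Aif1 at 1.39.

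Steroidogenic and theca genes were shifted down as a list with MEN (18 genes, median −0.31, mean −0.62, camera adjusted p = 0.0129; adjusted p = 0.262 with an estimated correlation). The median was −0.49 among arrays of low 18S signal and −0.71 without control 3. Star and Cyp11b1, the 11β-hydroxylase of glucocorticoid synthesis, fell, the latter at −2.03 ± 0.33, and the other 16 did not pass; adjusted over the list alone, 7 fell. Cyp11a1, which starts steroid synthesis from cholesterol, was at −3.82 ± 0.93 (adjusted p = 0.133), with control arrays spread by an SD of 2.08. Fdx1 lay at −1.03 ± 0.22 and Gli1 at 1.09 ± 0.56. fry, which tests whether the list moves 1 way, gave an adjusted p of 0.000744. The other falls by the fixed rule were Ly6d (−2.60 ± 0.38), Golt1b (−2.19 ± 0.31), the glycoprotein hormone subunit Cga (−2.03 ± 0.34), the proprotein convertase Pcsk5 (−1.96 ± 0.26), Cnnm1 (−1.82 ± 0.27), Fads6 (−1.76 ± 0.23) and Bptf (−1.72 ± 0.27). Of these Ly6d, Cga, Cnnm1 and Fads6, and Cyp11b1, lay below the median probe set with MEN, where the pseudocount bounds the size of a fall.

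Macrophage and leukocyte markers were shifted up with MEN (25 genes, median 0.53, camera adjusted p = 5.23e-08; adjusted p = 0.377 with an estimated correlation). Of its members 4 rose over all probe sets, Aif1, the mannose receptor gene Mrc1 (1.37 ± 0.20), Tyrobp (1.02 ± 0.13) and Cd53 (0.93 ± 0.16), and 8 when adjusted over the list alone. The list's median was 0.40 among arrays of low 18S signal and 0.42 without control 3. H2-Ab1, a class II antigen-presenting gene, rose by 1.46 ± 0.25. Stromal fibroblast markers were shifted up too (21 genes, median 0.34, adjusted p = 0.00642; adjusted p = 0.262 with an estimated correlation). The microfibril genes Mfap4 (1.32 ± 0.17) and Mfap5 (0.89 ± 0.15) rose, whereas Fbln2 lay at −1.02 ± 0.49. The median was 0.20 without control 3. Of the extracellular matrix list, whose median was 0.05 (adjusted p = 0.437), Postn rose by 0.76 ± 0.12. Endothelial and smooth muscle markers had medians of 0.03 and −0.08 (adjusted p = 0.752 and 0.852). Without control 3 these 2 medians were −0.25 and −0.20.

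Other lists shifted up with MEN were cell cycle genes (40 genes, median 0.21, adjusted p = 0.000295; 0.529 with an estimated correlation), PPAR and fatty acid oxidation genes (22 genes, median 0.17, adjusted p = 0.000295; 0.262 with an estimated correlation) and oocyte-specific genes (24 genes, median 0.34, adjusted p = 0.00837; 0.676 with an estimated correlation). No single member of these 3 lists passed over all probe sets. Adjusted over the list alone, 2 cell cycle and 7 fatty acid oxidation genes rose. Single members of the 3 lists lay at 0.62 ± 0.12 (Ccnb2, cyclin B2), 0.41 ± 0.10 (Ech1) and 1.64 ± 0.54 (Bmp15, an oocyte growth factor); no oocyte-specific gene passed either way. Within the low 18S class the medians were 0.24, 0.27 and 0.26. p53 targets were shifted down (30 genes, median −0.28, adjusted p = 0.0304; adjusted p = 0.529 with an estimated correlation). Of these Cdkn1a, the cell cycle inhibitor p21, fell by 1.55 ± 0.24 (adjusted p = 0.0353), and Mdm2 lay at −0.56 ± 0.19. The stress regulator Nupr1 fell by 1.49 ± 0.25 and hexokinase 2 (Hk2) by 0.93 ± 0.16, while the interferon-induced Ifit2 rose by 0.75 ± 0.12. The NRF2 antioxidant list was not shifted with any agent (MEN median −0.04, adjusted p = 0.646), with Hmox1 at 0.50 ± 0.29 (0.11 without control 3) and Nqo1 at −0.17 ± 0.15 with MEN. Gdf9 lay at 0.36 ± 0.18, Kitl at −0.44 ± 0.26 and Mki67 at 0.33 ± 0.31.

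The imprinted gene Plagl1 (2.01 ± 0.34), the noncoding RNA Xist (2.07 ± 0.29) and Mob3b (1.63 ± 0.20) also rose with MEN. For Xist 1 of 3 probe sets was called. For Plagl1, Golt1b and Cd53, 1 other probe set had the opposite sign. The count of 153 was 0 in a fit of the MEN and control arrays alone, 7 with the replicate block, 3 with the 18S class as a block and 0 among arrays of low 18S signal. The median size of these 153 changes was 1.08 over all arrays, 1.14 among arrays of low 18S signal and 1.08 without control 3. The 153 were chosen on these same arrays, with no overlap between MEN and control, so these sizes are no separate test. The count was 2 without control 2, 1 without MEN 1, 3 without MEN 2, 1 without MEN 3 and 708 without control 3; without control 3 it was 3474 with the 18S class as a block and 1950 among arrays of low 18S signal.

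**Figure D3:**
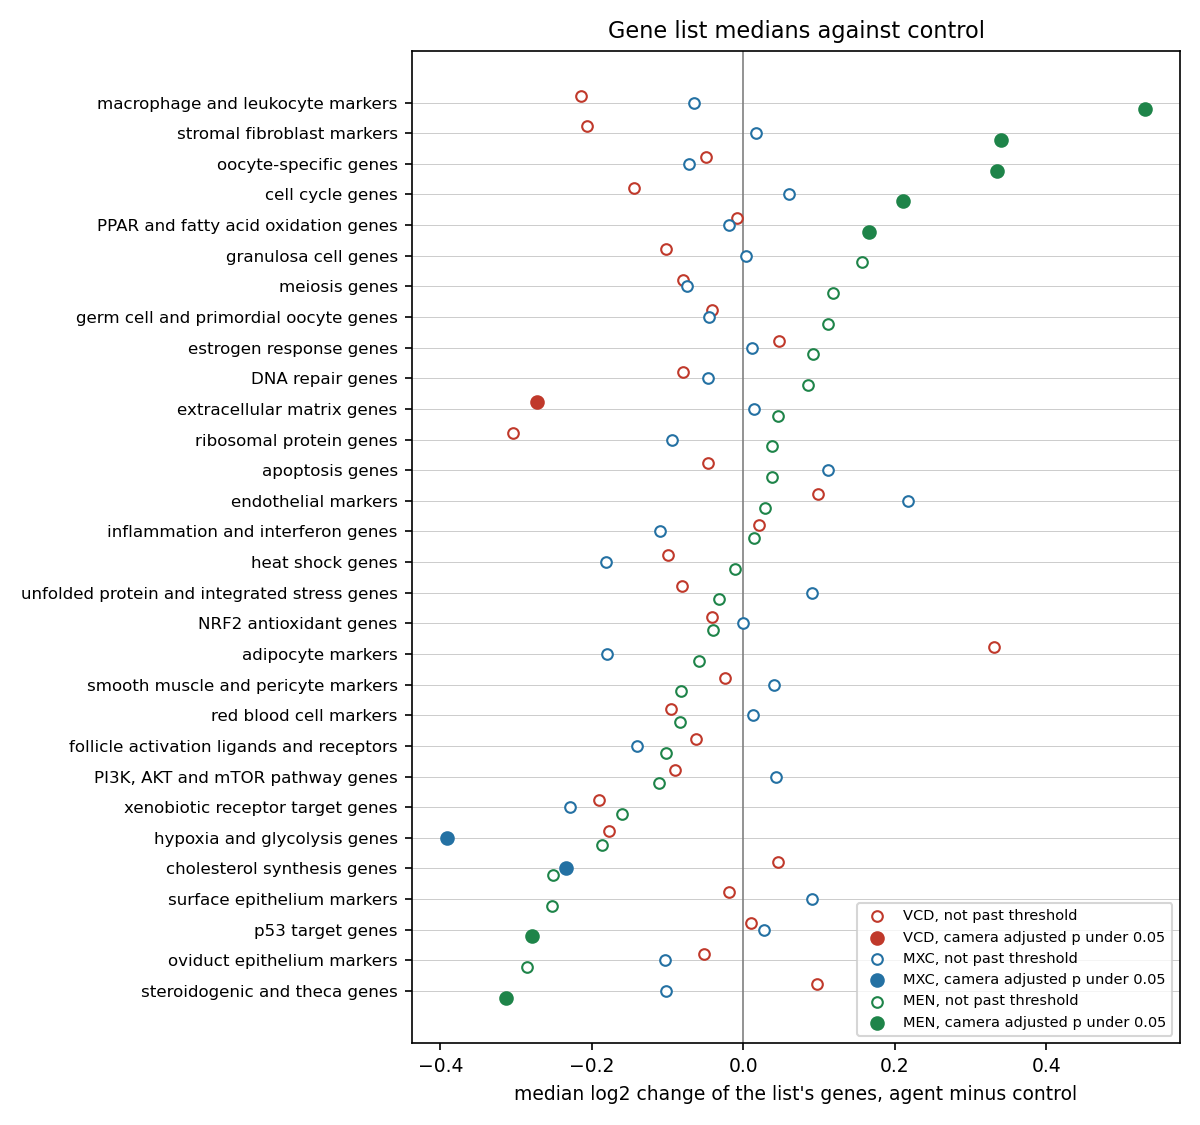
Median log2 change against control of each of the 30 gene lists fixed beforehand, for VCD, MXC and MEN; filled points passed camera at the preset correlation. Macrophage and leukocyte markers with MEN have the highest median among the filled points, 0.53, and hypoxia and glycolysis genes with MXC the lowest, −0.39.

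**Figure D4:**
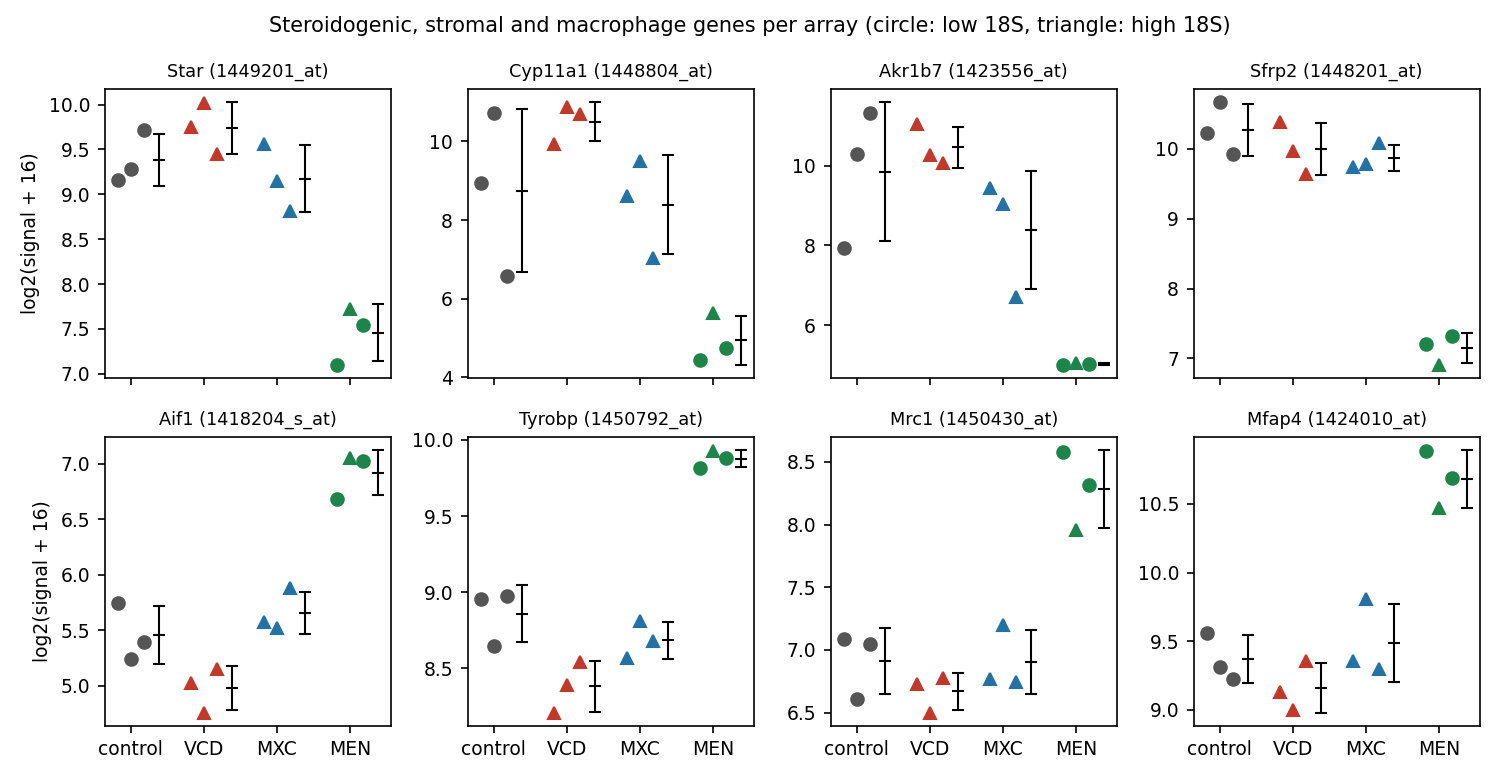
Log2(signal + 16) of 8 probe sets on each array by group, with the mean and SD of each group in black; circles are arrays of low 18S signal and triangles of high. MEN arrays lie apart from all others for each of the 8 probe sets, and control arrays of Cyp11a1 spread by an SD of 2.08.

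VCD and MXC, both at 50 µM and both in the high 18S class, had no probe set past the threshold between them (smallest adjusted p = 0.125; 4034 had an unadjusted p under 0.05). An unmoderated analysis of variance gave 0 as well, array weights gave 3455, actin as a covariate 140 (91.4% higher with VCD) and the 18S class as a block without control 3 gave 26. The 3 VCD and 3 MXC arrays did not overlap at 21.9% of probe sets, against an average of 10% by chance. Probe sets are not independent, so a single grouping of arrays can lie far from that average. These arrays also did not overlap in actin ratio (at most 1.49 with VCD, at least 1.82 with MXC) or median signal (at least 32.4 and at most 31.1).

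VCD (50 µM) and MEN (5 µM) differed at 2118 probe sets, 1384 higher with VCD and 734 lower. The steroidogenic genes Cyp11a1 and Akr1b7 were higher with VCD by 5.57 ± 0.93 and 5.42 ± 0.85 (log2; adjusted p = 0.0127 and 0.0105), and with MEN Akr1b7 lay at 5.04 ± 0.02 (SD, n = 3). Of the 2 other Cyp11a1 probe sets, 1 had the opposite sign. The neuropeptide gene Cck, the growth factor gene Ereg and the prostaglandin synthase Ptgs2 were higher with VCD by 4.38 ± 0.81, 3.67 ± 0.64 and 3.52 ± 0.67. With MEN, Ptgs2 (4.33), Cck (4.87), Cyp11a1 (4.93) and Akr1b7 lay below the median probe set, so the sizes of their differences depend on the pseudocount. Lower with VCD were Reg3b (−2.50 ± 0.52), the Fc receptor gene Fcgr2b (−2.34 ± 0.25), the class II invariant chain Cd74 (−2.33 ± 0.41), Fcrls (−2.10 ± 0.33) and Phex (−2.08 ± 0.34). Of 25 macrophage and leukocyte markers 8 were lower with VCD than with MEN, as were 4 of 21 stromal markers, and 4 of 18 steroidogenic genes were higher. The direction of the calls depended on scaling: 65.3% were higher with VCD as deposited, 37.5% of 1815 after quantile normalization and 18.2% of 4550 after subtraction of array medians. Among arrays of high 18S signal, which hold 1 MEN array, 1 probe set was called, and 1 with the 18S class as a block. Leaving out 1 array gave 293 (without MEN 3) to 3813 (without MEN 2) calls.

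MXC (50 µM) and MEN (5 µM) differed at 467 probe sets, 180 higher with MXC and 287 lower. Sfrp2 was higher with MXC by 2.72 ± 0.23 (adjusted p = 0.00595), as were the lens crystallin Crygb (2.18 ± 0.44), the orphan nuclear receptor Nr4a1 (2.07 ± 0.40), Sox4 (1.97 ± 0.30) and Vsig8 (1.93 ± 0.35). For Sox4, 1 of 7 other probe sets was also called and 2 had the opposite sign. Ogn (−2.27 ± 0.35), the retinol acyltransferase Lrat (−1.76 ± 0.34), Phex (−1.72 ± 0.34), the retinaldehyde dehydrogenase Aldh1a3 (−1.68 ± 0.19) and the deiodinase Dio2 (−1.64 ± 0.24) were lower with MXC. Of 25 macrophage and leukocyte markers 5 were lower with MXC. Calls higher with MXC made up 38.5% as deposited, 25.4% after quantile normalization and 18.4% after subtraction of array medians. The count was 0 in a fit of these 6 arrays and with the 18S class as a block, 1 among arrays of high 18S signal, 0 without MXC 1 and 1068 without MEN 2.

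A single probe set, of Xist, was called for VCD and MEN in the same direction, at 2.01 ± 0.29 and 2.07 ± 0.29; with MXC it stood at 2.35 ± 0.29 (adjusted p = 0.382). Independent lists would share 0.314 rises. Simulated unchanged groups had no calls for any agent in any of 20 draws, so the 0 they shared was fixed by that and is no baseline. MXC had no calls to share, and 0 probe sets were called for all 3 agents. Across probe sets, which are not independent replicates, log2 changes of VCD and MXC correlated at 0.725, of VCD and MEN at 0.363, and of MXC and MEN at 0.441. The correlations with MEN depended on single arrays: for VCD and MXC they were 0.0314 and 0.157 without MEN 2, 0.565 and 0.638 without control 1, 0.603 and 0.657 without control 2, and 0.209 and 0.355 without control 3. Simulated unchanged groups, which shared 3 simulated controls, gave 0.796, 0.813 and 0.751. The observed covariance exceeded the simulated one by 0.042 for VCD and MXC and lay below it for the pairs with MEN, by −0.0175 for VCD and −0.0173 for MXC. The 3 controls cannot be divided into sets of at least 2 arrays, so part of any excess may come from the shared controls.

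The authors' deposited tables, from another normalization and counted without the control probe sets of the array maker, list 1095 probe sets higher and 31 lower with VCD, 325 and 105 with MXC, and 272 and 287 with MEN, at a fold of 2 or more and an unadjusted p under 0.05. After Benjamini-Hochberg adjustment of the deposited p-values, 0, 0 and 30 pass. The deposited changes correlated with those of the fit at 0.908, 0.904 and 0.898 across probe sets. In the authors' deposited table for MEN, Sfrp2 has a log2 change of −3.0, Star −1.69 and Aif1 1.71. The term with the highest enrichment score in the authors' deposited table for MEN is the MHC protein complex, with 7 of 23 genes listed.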

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

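Every test in this part was chosen after the result was seen, except the other splits of the arrays and the planned count for VCD without control 3. The margin of 2 standard errors used for labelling in the patterns with MEN was also set after the values were seen. For the rises with VCD, the test of integrity replaced 1 earlier form and that of scaling 2, after their outcomes were seen, because those forms could not decide. Control probe sets for mouse RNA, 19 in all, belong to no comparison of the report and were examined because a signal there was above the level of every control array. Every VCD array exceeded every control array for 18S ribosomal RNA, by at least 2.27 on the log2 scale at the 3′ probe set, 3.47 at the 5′ probe set and 2.10 at the middle one. The same held for the 5′ probe set of actin, by 1.03, and the 3′ probe set of the transferrin receptor, by 1.17. Every MXC array exceeded every control array for 18S by at least 1.80 (3′), 2.22 (5′) and 1.59 (middle). No group had more than 3 arrays, so single arrays were not tested as outliers.

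The first pattern is that rises with VCD outnumbered falls, 181 against 2, with a mean rise of 1.41 over control. With the actin difference as a covariate, rises were 76.5% (jackknife SE 6.26) of all probe sets with an unadjusted p under 0.05, and 89.5% of 1281 calls. Without the covariate they were 79.8% (SE 14.7). At the deposited scaling these values argue against a linear effect of the actin difference as the whole cause. The actin difference was at most 0.57 on VCD arrays and at least 1.06 on controls, so integrity and group are separated. Other forms of an integrity effect therefore stay open. Scaling stays open: centring by itself moves the share over all probe sets (to 45.1% after quantile normalization), and the calls after quantile normalization without control 3, 80.3% of 117 higher, were too few to decide, with 83.6% of 55 without VCD 3 as well, 0 calls without VCD 1 or VCD 2, and 25.5% of 47 and 0 calls without control 2 or control 1, which leaves 1 control. A labelling difference like that in the 18S signal stays open and cannot be told apart from VCD, because all VCD arrays were of the high class and all controls of the low. On MEN 2, of the high class, these probe sets averaged 0.514 above MEN 1 and 3, 36.6% of the rise with VCD. MXC 3 stood at 5.87 and VCD 3 at 6.61 with 18S signals of 9.64 and 9.68. These arrays also differed in integrity (actin ratio 5.34 and 1.49), and the probe sets were chosen for VCD. The pair therefore cannot weigh against class as the whole cause. An effect of VCD also stays open, and without control 3 rises were 94.3% of 682 calls, or 87.7% of 1477 with the actin covariate.

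The second pattern is that adrenal cortex markers were lower with MEN (14 measured genes, mean −1.24, median −0.74), in a list written after a first look, of which 8 genes are also in a fixed list and 12 lie above the median probe set in controls. Integrity is argued against by predicted changes of 0.122 over all arrays and −0.007 without control 3. Labelling as in the 18S signal is argued against by the change among arrays of low 18S signal, −1.30 ± 0.25 (SE). Adrenal tissue on the ovaries of the other groups may contribute and stays open: Cyp21a1, Cyp11b1, Cyp11b2 and Mc2r had a median change of −0.443, but only 2 of these 4 lay above the median probe set in controls (Cyp21a1 5.53, Cyp11b1 6.50, against 5.47). A lower steroidogenic expression in ovaries given MEN stays open as a hypothesis.

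The third pattern is that macrophage and leukocyte markers were higher with MEN (25 genes, mean 0.554). Integrity is argued against by a predicted change of 0.152, at most 0.290. A lower share of the main cell types would raise the stromal, endothelial and smooth muscle lists alike. The smooth muscle median of −0.0823 and the endothelial median of 0.03 lay 3.23 and 3.09 standard errors below the macrophage median of 0.53. The stromal median of 0.34, at 0.919 standard errors, would go with that explanation. These standard errors run over the genes of the lists, taken as independent, and leave out the spread between arrays. They therefore cannot decide, and a lower share of the main cell types stays open. Labelling as in the 18S signal stays open, because the change among arrays of low 18S signal was 0.483 with an SE of 0.255. More macrophages or more expression per macrophage with MEN, as a hypothesis, was not separated from labelling, from cell share or from a part due to integrity.

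Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. Fitted on the 6 arrays of VCD and control, the real split gave 439 probe sets and the highest other split 0, so 1 of 10 splits was as large. For VCD and MEN the real split gave 4397 and the highest other 0, again 1 of 10. For MXC and control, MEN and control, and VCD and MXC, the real split and the highest other gave 0, so 10 of 10 were as large. For MXC and MEN the real split gave 0 and the highest other 505, with 10 of 10 as large; that split set MXC 1, MXC 2 and MEN 2, the 3 of these 6 arrays with the lowest actin ratio, against MXC 3, MEN 1 and MEN 3, and so points to a structure of the arrays other than the agents. Among gene lists, the real split shifted 1 with VCD and the highest other 8 (10 of 10 as large), 2 and 7 with MXC (7 of 10), and 11 and 8 with MEN (1 of 10).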

How the results depend on the processing

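Alternatives that use other pseudocounts, actin as a covariate, removal of degraded arrays or the 18S class were chosen after seeing the data; the others were planned. The planned use of per-array values from the authors' workbooks was not run, because those tables hold none. For these results the cause was not tested, apart from the tests of the flagged patterns and the other splits of the arrays given above. The counts of called probe sets against control were 183 (VCD), 0 (MXC) and 153 (MEN), between agents 0, 2118 and 467, 1 was shared by VCD and MEN, and 1, 2 and 7 lists were shifted by VCD, MXC and MEN.

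Quantile normalization gave 2 for VCD, 0 shared by VCD and MEN, and 6 lists with VCD. Subtraction of array medians gave 17 for VCD, 4550 for VCD against MEN, 915 for MXC against MEN, 0 shared and 1 list with MXC. Without dim probe sets 0 lists were shifted by VCD. Fits of the compared groups alone gave 439 for VCD, 0 for MEN, 4397 for VCD against MEN, 0 for MXC against MEN and 0 shared. An intensity trend gave 297, 76 for MEN and 78 for MXC against MEN. Array weights were lowest for control 3 (0.0815) and highest for MXC 1 (5.64) and MEN 3 (3.25). They gave 4026, 2701 and 6637 against control, and 3455, 17012 and 16070 between agents. With them 1322, 286 and 421 were shared by VCD and MXC, VCD and MEN, and MXC and MEN, and 102 by all 3. An unmoderated analysis of variance gave 25, 6 for MEN, 1085 and 167 for VCD and MXC against MEN, and 0 shared. At an adjusted p under 0.01 there were 0 for VCD, 1 for MEN, 288 and 2 against MEN and 0 shared. At 2-fold there were 88 for MEN, and 887 and 187 against MEN. With 1 probe set per gene there were 1 for VCD, 802 for VCD against MEN and 0 shared. With an estimated correlation 0, 0 and 0 lists were shifted by VCD, MXC and MEN, with fry 0, 0 and 1. With the probe set of largest variance 8 lists were shifted by VCD and 5 by MXC, and the cholesterol synthesis median with MXC was 0.05; with the mean of probe sets 7 were shifted by VCD.

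A pseudocount of 1 gave 117 for VCD, 10 for MEN, 1146 and 1 against MEN and 1 list with MXC; 32 gave 3 shared. Actin as a covariate gave 1281, 1524 for MEN, 140 between VCD and MXC, 6872 and 4592 against MEN, 72 shared, correlations of 0.567 (VCD and MXC) and 0.282 (MXC and MEN) and 3 lists with VCD. Without control 3 and MXC 3 there were 1512, 1386 for MEN, 8264 and 1971 against MEN, 92 shared, a correlation of 0.209 (VCD and MEN), 2 lists with VCD and 4 with MXC. Without control 3 and with the actin covariate there were 1477, 2084, 5245, 5186, 158 shared and 3 lists with VCD. Without control 3 and with quantile normalization there were 117, 584, 1 between VCD and MXC, 4730 and 2876 against MEN, 9 shared, correlations of 0.575 and 0.196 and 4 lists with VCD. The 18S class as a block gave 0 for VCD, 3 for MEN, 1 and 0 against MEN, 0 shared, a correlation of 0.605 for VCD and MXC, 2 lists with VCD and 4 with MXC. With control 3 also left out it gave 0, 3474, 26 between VCD and MXC, 546 and 5 against MEN and 0 shared. Correlations for the pairs with MEN were then 0.574 and 0.646, with 3 lists for VCD and 4 for MXC. In both block fits the comparisons of VCD and MXC with control or MEN rest on MEN 2. Their counts therefore cannot show a dependence on class. Arrays of low 18S signal gave 0 for MEN, and 1950 without control 3; arrays of high 18S signal gave 1 and 1 for VCD and MXC against MEN.

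Leaving out 1 array at a time gave 0 to 682 for VCD, 0 to 1 for MXC and 1 to 708 for MEN, the highest for VCD and MEN without control 3. Between agents the ranges were 0 to 0, 293 to 3813 and 0 to 1068. Shared calls ranged from 0 to 1 (VCD and MXC), 0 to 23 (VCD and MEN), 0 to 1 (MXC and MEN) and 0 to 1 (all 3). Correlations ranged from 0.607 to 0.831, 0.0314 to 0.603 and 0.157 to 0.657, and shifted lists from 0 to 2, 1 to 4 and 5 to 8.

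Beyond control and MXC, the replicate numbers did not meet the rule for pairing: over all groups 8 of 18 same-number pairs correlated above 0.1 (median 0.0928, range −0.273 to 0.581), as did 9 of 36 pairs of different number (median −0.0741), and 7 of 12 arrays correlated best with their own number. With the replicate block 225 probe sets were called for VCD, 0 for MXC, 7 for MEN, 0 between VCD and MXC, 2234 for VCD against MEN, 337 for MXC against MEN and 0 shared, and 2 lists were shifted by VCD.

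Lists called at the preset correlation kept the direction given by the test in 294 settings, of which 241 kept the call and 53 lost it, although the cholesterol synthesis median changed sign as said above. Named genes past the threshold kept their call in 718 of 1300 settings and their direction in all of them. They were chosen on these same arrays with no overlap between the groups, so leaving out an array could not turn their direction. Genes that had not passed did so in 4 of 1072, and their signs often changed. Of 85 other probe sets of called genes, 14 were also called, 55 had the same sign and 16 the opposite sign. With VCD these were Sox4 (−0.32), Rbbp4 (−0.42), Sbno1 (−0.21), Slc39a6 (−0.40), Mga (−0.40), Atrx (−0.32), Zfp451 (−0.29, −0.0999 and −0.0795) and Tbc1d9 (0.46). With MEN they were Plagl1 (−0.18), Golt1b (0.14) and Cd53 (−0.0791), for VCD against MEN Cyp11a1 (−0.19), and for MXC against MEN Sox4 (−0.00336 and −0.0962). The number of arrays limits what could be called: 1.5-fold changes were called in 6% to 12% of simulated cases.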

Other observations

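The 4 lists described here were written after a first look at single probe sets, so their tests are not independent of the data. Their p-values were adjusted over the tests of these 4 lists alone. That family is smaller than the 90 tests of the fixed lists, so adjusted p-values cannot be compared between them. Genes induced by cyclic AMP were lower with MEN (22 genes, median log2 −0.55, camera adjusted p = 1.5e-06; adjusted p = 0.167 with an estimated correlation), and the median among arrays of low 18S signal was −0.64. None passed over all probe sets, and 7 fell and 1 rose when adjusted over the list alone. Ereg, an EGF receptor ligand gene, lay at −3.44 ± 0.64, the nuclear receptor gene Nr4a1 at −1.96 ± 0.40, the phosphodiesterase Pde4b at −1.85 ± 0.37 and the inhibin subunit Inhba at −1.69 ± 0.33. With VCD the median of this list was 0.17 and with MXC −0.35 (adjusted p = 0.00463 and 0.0218; 0.306 and 0.394 with an estimated correlation). VCD minus MEN had a median of 1.12, with 6 of 22 genes higher with VCD.

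Within the smaller family of the added lists, adrenal cortex markers with MEN were called with an estimated correlation too. The camera adjusted p was 4.83e-08 at the preset correlation and 0.00705 with an estimated one. Whether the latter call would hold in a family of 90 tests, as used for the fixed lists, was not tested. Akr1b7, an aldo-keto reductase gene, lay at −4.81 ± 0.85 (adjusted p = 0.0561), and Mrap, the accessory protein of the ACTH receptor, at −1.83 ± 0.35. With VCD the list's median was 0.22 (adjusted p = 0.0477; 0.22 with an estimated correlation) and with MXC −0.29 (0.0153; 0.167 with an estimated correlation). Mast cell markers with MEN had a median of −0.41 (10 genes, adjusted p = 0.000191, and 0.167 with an estimated correlation). Without control 3 their median was −0.64. All 10 were below control, led by Hdc, the histamine-forming enzyme (−1.33 ± 0.29), and the monoamine transporter Slc18a2 (−1.33 ± 0.29), and with VCD and MXC the adjusted p was 0.992 and 0.392. B cell and lymph node markers had medians of −0.27 with VCD, −0.22 with MXC and −0.28 with MEN (23 genes; adjusted p = 0.000539, 0.00025 and 5.43e-05; 0.299, 0.299 and 0.266 with an estimated correlation). Only 5 of these 23 lay above the median probe set in controls, and H2-Ob alone fell, with MEN, by 0.97 ± 0.12.

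In the authors' deposited table for VCD the Gene Ontology terms with the highest scores are broad ones, with 332 of 4155 genes of the term intracellular organelle listed. For MXC the first is regulation of macromolecule metabolic process, with 87 of 1861. Their p-values come from the same arrays, in which VCD and MXC cannot be told apart from 18S class.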
